A study of Drosophila melanogaster with 3 samples.

How the data were processed

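Chromatin immunoprecipitation followed by sequencing was carried out, per the labels, on whole prepupae of a transgenic line that expresses fkh with a C-terminal green fluorescent protein, with an antibody to that protein. Chromatin was sheared by sonication, per the labels. The 3 samples are biological replicates of 1 group, per the labels, and each pools males and females. The labels also give an age of 24 days, longer than development to the prepupa takes, so its unit is in doubt and it was not used here. The replicates' numbers are those of the labels.

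The peak lists that the authors deposited were used, and reads and coverage were not used here. Per the deposited file lists, each replicate was called against 1 control shared by the 3 replicates, a further list was called on the 3 replicates together, and the optimal list was made from these by a reproducibility (IDR) step. All of this was done on the dm6 build and again on dm3, which gives 10 lists. The aligner, the peak caller, the IDR threshold and the origin of the control are not given in the sources used here. In the deposited lists each region has a signal, a score on a scale that is not stated, and a value of −log10 of the q-value. The deposited −log10 values reached their maximum of 4.289 in all 9531 peaks of the optimal dm6 list, so peaks were ranked by the authors' signal score. Signals of lists called separately are not on one scale, so replicates were compared by rank. The exceptions are 1 alternative, Pearson's correlation of log2 signal, and the ratio of the strongest to the median signal within each list. The 30000 regions in each replicate and pooled list include background, per the deposited file lists, and the number is the same in every such list, so it is not a count of binding sites. Read depth was not given in the lists, and no interval here covers more than counting error.

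Coordinates are those of the deposited dm6 lists, written 1-based. Their sequence was the release 6 assembly, and genes were taken from Ensembl release 115. The dm3 lists were used for counts and strengths only, and no coordinates were converted. Overlap meant at least 1 shared bp, and K, the number of strongest regions taken per replicate, was 9531, the size of the optimal list. An optimal peak was given the best rank among the regions of a replicate that it overlapped. In the optimal dm6 list 9531 peaks lay in 8728 distinct intervals, so several summits of one interval share their replicate ranks.

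Replicate overlap was tested against 1000 relocations of the regions within their chromosome. Summits were put into the first fitting class of promoter (within 500 bp of a TSS), 5' UTR, coding sequence (CDS), 3' UTR, intron, other exon and intergenic, and tested two-sided against 10000 relocations in sequence without N. Words were searched on both strands within 50 bp of the summit and in a window 500 bp to a side drawn at random with a fixed seed, with a two-sided exact McNemar test. Values under 1e-300 were written as that bound. Strength was compared between the strongest and the weakest of 5 quintiles with two-sided Fisher's exact tests. A gene counted as having a peak if a summit lay within 1000 bp of any of its TSSs, so a peak between close genes counted for each of them. The 23 gene lists, the 18 words, the tests, the rule for named genes and the alternatives, except those said to be chosen later, were fixed before the data were examined. Each list was tested against all other protein-coding genes with a two-sided Fisher's exact test. Other lists held 6 of the salivary gland regulators, 4 of the gut regulators, 4 of the Hox genes and cofactors, 3 of the Fox family and 1 each of the insulin and TOR, fat body and trachea lists. Outdated gene symbols were matched to current ones after the files were opened. P-values called adjusted, and those listed after them in the same series, were adjusted by the Benjamini-Hochberg method within their family. The others were not adjusted. With 1 group there was no comparison between groups of samples.

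The genes named were fkh, the protein-coding genes nearest to the strongest peaks within 1000 bp of a TSS up to 10 genes, and up to 4 members of each list with the strongest peaks. The genes with the most peaks in the closing section were chosen after their values were seen. Alternatives covered the build, the strength and number of peaks, the overlap required, each replicate left out (peaks shared by both others), the widths of all windows, the comparison sets, the assignment of peaks to genes and stratification by gene length with a Cochran-Mantel-Haenszel test. The steps were tested on simulated data for the 13968 protein-coding genes. A list of 40 genes, of which 20 were given a peak and 25 had one, was called with a Fisher's exact p of 1.91e-10, and 4% of 200 random lists passed an unadjusted 0.05. Relocated peaks gave a promoter ratio of 0.978, and a set made to have 1.67 gave 1.69. The forkhead word planted at 20% of 2000 random positions of chromosome 4 was found at 44.5% of them and 31.2% of their flanks (exact McNemar p = 1.79e-18), and without planting at 27.9% and 28.7% (0.595). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.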

Results

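Binding of the forkhead transcription factor fkh was mapped by ChIP-seq in whole prepupae of Drosophila melanogaster, the stage at which the larva has stopped feeding and metamorphosis begins. fkh is the founding member of the forkhead (Fox) family and is known for its part in the development of the salivary glands and the gut. The flies carried fkh fused at its C terminus to green fluorescent protein, and chromatin was precipitated with an antibody to that tag. The series holds 1 group of 3 biological replicates of pooled males and females, so the comparisons are between replicates, between peaks and the rest of the genome, and between groups of genes. On the dm6 build, each replicate list and the list from the 3 replicates together held 30000 regions, and the authors' optimal list, kept after their reproducibility step, held 9531 peaks. These 9531 peaks were the 9531 strongest regions of the pooled list by the authors' signal, which ran from 160 to 6080.8 with a median of 294.1. The lists give no read counts, so the sequencing depth behind each value is unknown, and every interval below covers counting error only.

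The strongest peak of the genome lay at fkh itself (FBgn0000659, 3R, 28580976 to 28585264 on the minus strand, dm6). Its interval spanned 28584588 to 28588088 with the summit at 28585478, in the promoter 214 bp from a transcription start site (TSS), and its signal was 6080.8. It ranked 1 in each of the 3 replicates. Within 10 kb of the gene there were 14 peaks, against a median of 2 for the protein-coding genes, which placed fkh at percentile 99.39 by the number of peaks. Within 5 kb there were 6 peaks, at percentile 94.42, and within 20 kb 27, at percentile 99.91. These counts are of summits, and several summits here share an interval, as those at 28585478 and 28587065 do. The counts were not repeated with close summits left out. Upstream of the gene, summits at 28587065 and 28590706 had signals of 2232.9 and 2198.7, both in exons of non-coding RNA genes, and an intergenic summit at 28597768 had 1547.6. Downstream, the strongest summit within 20 kb lay in intergenic sequence at 28571035 with a signal of 1434.4, and a stronger one lay beyond that window at 28547373 with 2921.8. The labels give an insertion that targets fkh. Its extent, and whether it adds a copy of the gene, are not given in the sources used here, so which of these summits it covers is unknown.

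**Figure D1:**
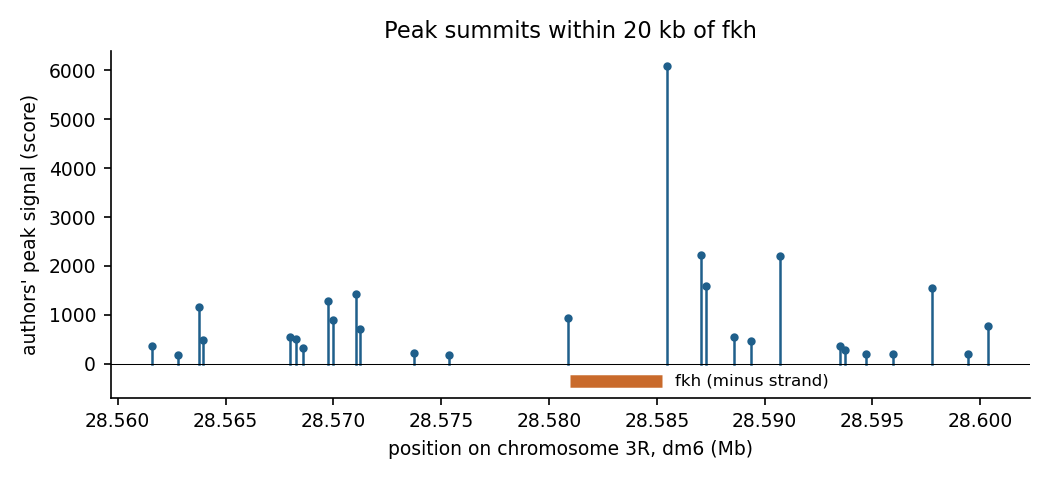
Authors' peak signal (y axis, score) of each peak summit within 20 kb of fkh against its position on 3R of dm6 (x axis, Mb), with the gene drawn as a bar below the axis. The highest of the 27 summits, at 6080.8, stands just upstream of the gene.

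The 3 replicates gave largely overlapping regions. Of the 9531 strongest regions of each replicate, 81.7% overlapped between replicates 1 and 2, 81.5% between replicates 1 and 3 and 79.9% between replicates 2 and 3, as the mean of both directions. Random relocation of the regions gave means of 4.98% to 5.06% and at most 5.76% in 1000 draws, and the permutation p of 0.001 is the smallest that number can give for each pair. Relocation does not allow for regions that recur because the 3 lists were called against 1 shared control. The ranks of the optimal peaks correlated across peaks with Spearman's rho of 0.783, 0.800 and 0.809 for the same pairs. Peaks are not independent replicates, so no p is given for rho. Of the 9531 optimal peaks, 6951 (72.9%, exact 95% interval 72.0% to 73.8%) overlapped one of the 9531 strongest regions in all 3 replicates, 1774 in 2 replicates, 763 in 1 and 43 in none. This share depended on the strength of the peak and was 99.4% in the strongest quintile and 23.7% in the weakest. The optimal list was made from these same replicates by the reproducibility step, and its signal was called on the 3 together. Agreement at strong peaks, its loss near the cut, and rho are therefore partly built in. Requiring 50% of each region to be shared lowered the overall share to 36.7%, and taking all 30000 regions of each replicate raised it to 98.2%.

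Peaks lay mainly at promoters and in introns. Of the 9531 summits, 4229 (44.4%) were within 500 bp of a TSS, against 13.5% ± 0.356 (SD of 10000 random relocations within the same chromosome), a ratio of 3.29 (adjusted permutation p = 0.0003, from the smallest p those relocations can give). Coding sequence held 39 summits (0.409%, against 13.7% at random), 3' UTRs 134 (1.41% against 4.38%) and intergenic sequence 1105 (11.6% against 27.4%), each with the same adjusted permutation p of 0.0003. Summits in 5' UTRs, 117 in number, were above random (1.23% against 0.773%, adjusted permutation p = 0.0003), but the ratio fell to 1.06 against the pooled-list regions that shared no base with an optimal peak (Fisher's exact p = 0.597, not adjusted), and the call was lost in the 4766 strongest peaks (adjusted permutation p = 0.0676) and with a promoter window of 1000 bp (0.616). Introns held 3827 summits (40.2%), which was not told apart from the 39.4% of random positions (adjusted permutation p = 0.141). This depended on the promoter window: introns were above random with 250 bp (ratio 1.10, adjusted permutation p = 0.00117) and below with 1000 bp (0.926, adjusted permutation p = 0.0014). They were also above random without summits within 300 bp of a stronger one, an alternative chosen after the data were seen (1.04, adjusted permutation p = 0.007). The 17575 pooled-list regions outside the optimal list had 19.3% of summits at promoters and 52.5% in introns. They also had few in coding sequence (1.33%) and 3' UTRs (2.94%), and 21.7% in intergenic sequence. Much of the shortfall in coding sequence against random positions was therefore shared with these regions and is not particular to the peaks. The median distance from a summit to the nearest TSS was 727 bp for the optimal peaks and 2319 bp for those regions.

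**Figure D2:**
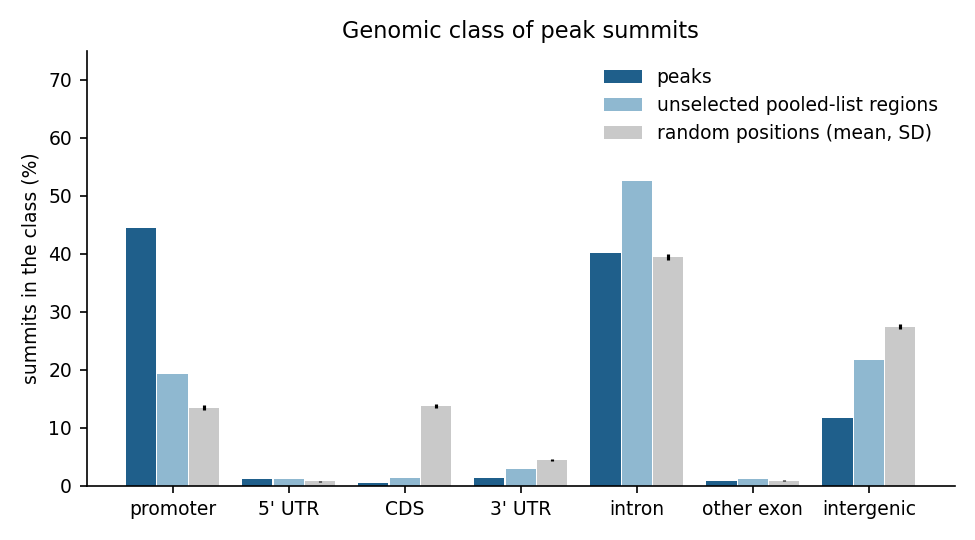
Share of summits in each genomic class (y axis, percent) for the 9531 peaks, the 17575 pooled-list regions outside the optimal list, and random positions on the same chromosomes (mean and SD of 10000 relocations). Promoters held 44.4% of peaks against 13.5% of random positions, and coding sequence 0.409% against 13.7%. Coding sequence held 1.33% of the regions outside the optimal list.

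The forkhead recognition word and its variants gave the smallest p of the words tested (exact McNemar test), while the DRE, described below, had a higher ratio to its flanks. TRTTTRY, the core bound by Fox proteins (R is A or G, Y is C or T), was present within 50 bp of 58.5% of 9530 summits and in 25.3% of windows of the same width 500 bp away, a ratio of 2.31 (exact McNemar p below 1e-300). It ranked 1 by this ratio among 105 arrangements of its own letters, whose other members had a median ratio of 1.09 and a highest of 2.09. The one with that highest ratio, YTRTTTR, is a shifted copy of the word. GC content was 41.5% at the summits and 41.0% in the flanks. The narrower word TGTTTAY was present in 6.002% of flanks and 20.6% of summits (adjusted exact McNemar p = 8.95e-199), and the wider TRTTKRY in 33.2% and 66.9% (exact McNemar p below 1e-300). The forkhead word was also present in 41.7% of the regions outside the optimal list, less often than in the optimal peaks (Fisher's exact p = 4.08e-155).

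**Figure D3:**
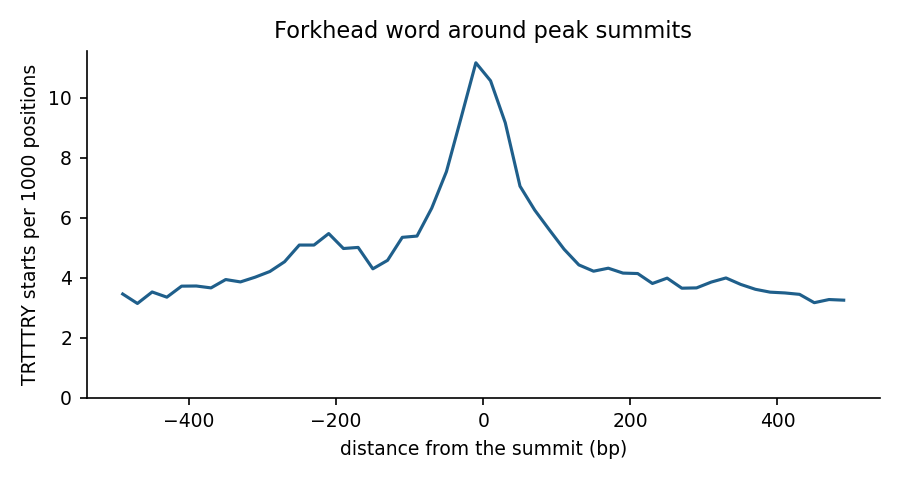
Occurrences of the forkhead word TRTTTRY per 1000 positions (y axis), in 20-bp steps by distance from the summit (x axis, bp), over the optimal peaks. Each occurrence, on either strand, was placed at its middle base, although the axis names starts. The density was 11.2 in the step that ends at the summit, 3.46 at the left end and 3.25 at the right end, with a second rise to 5.47 at 200 to 220 bp left of the summit.

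Among the 15 other words tested, 5 were above their flanks and 5 below. The DRE, the word of the promoter factor DREF, was found at 1.70% of summits against 0.241% of flanks, a ratio of 7.04 (adjusted exact McNemar p = 2.21e-26). The CA repeat was in 9.16% of flanks and 16.8% of summits (adjusted exact p = 2.07e-56), the GAGA word in 12.1% and 16.9% (7.27e-21), the GATA word in 14.2% and 16.9% (1.25e-06) and the E-box in 40.2% and 43.3% (3.34e-05). The homeodomain word, the nuclear receptor half-site AGGTCA, the FTZ-F1 word, the Mef2 word and runs of A were less frequent at summits than in flanks, with ratios from 0.573 to 0.888 (adjusted exact p from 7.33e-05 to 0.00571). The words for CRE-binding factors, AP-1, Grh, Zelda and the TATA box did not pass the threshold (adjusted exact p from 0.0591 to 1). Against the regions outside the optimal list, the E-box (43.3% against 42.1%, Fisher's exact p = 0.0658, not adjusted) and the Mef2 word (2.84% against 3.08%, 0.28) did not pass either. The CRE word, which did not pass against its flanks, was more frequent than in those regions (2.89% against 2.40%, Fisher's exact p = 0.0158, not adjusted).

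Strong peaks carried the forkhead word and lay at promoters more often than weak ones. The word was present at 69.8% of summits in the strongest quintile by signal (exact 95% interval 67.7% to 71.9%) and 51.5% in the weakest (49.2% to 53.7%), an odds ratio of 2.18 (Fisher's exact p = 2.53e-31), while its flanks held 25.2% and 23.7%. Promoters took 52.0% of the strongest quintile and 35.9% of the weakest, an odds ratio of 1.94 (Fisher's exact p = 1.03e-23). Promoter peaks nonetheless held the word less often than all other peaks, 51.4% against 64.3% (Fisher's exact p = 7.63e-37). The ratio to their own flanks was 2.34 for promoter peaks and 2.25 for the others.

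**Figure D4:**
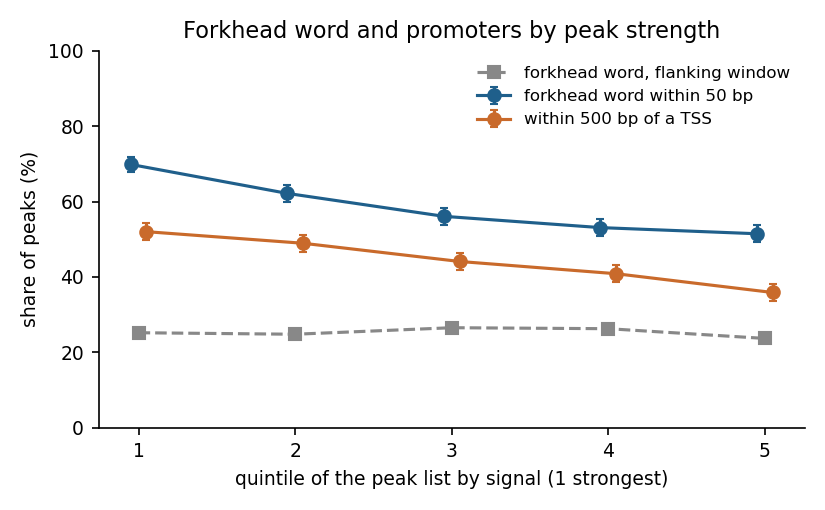
Share of peaks (y axis, percent) with the forkhead word within 50 bp of the summit or with the summit within 500 bp of a TSS, by quintile of the authors' signal (x axis, 1 strongest), with exact 95% intervals, and the share of flanking windows with the word. The word fell from 69.8% to 51.5% and promoters from 52.0% to 35.9%, while the flanks stayed between 23.7% and 26.5%.

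Of 13968 protein-coding genes, 4345 (31.1%) had a peak within 1000 bp of a TSS. After fkh, the protein-coding genes at the strongest such peaks were CG14100 (FBgn0036889, signal 2900.9, summit 84 bp from the TSS), CG15814 (FBgn0030873, 2809.3, 27 bp), the kinase gene fray (FBgn0023083, 2681.2, 330 bp) and the junctophilin gene jp (FBgn0032129, 2665.6, 774 bp). They were followed by CG7966 with a signal of 2407.8, Ccz1, a factor of late endosome maturation, with 2258.6, the calpain gene CalpA with 2215.2, the forkhead gene FoxK with 2122.2 and CG13185 with 2089.5. The peak of rank 2, with a signal of 3929.2, lay 17 bp from the TSS of the non-coding RNA gene lncRNA:CR31840, which was named after its value was seen. The summits at fkh, CG14100 and CG7966 had no forkhead word within 50 bp, and the other 7 protein-coding genes did. These genes ranked high in every replicate: the mean rank was 8 ± 5 (SD, n = 3) for CG14100 and 9.33 ± 3.06 (SD, n = 3) for fray. The most variable was FoxK, at ranks 21, 88 and 20.

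Salivary gland regulators and genes of the secretory pathway machinery had a peak more often than other genes. The chromatin came from whole prepupae, so these peaks cannot be placed in the gland. Of 15 salivary gland regulators, 10 had a peak at a TSS (66.7%, exact 95% interval 38.4% to 88.2%, adjusted Fisher's exact p = 0.0283), with fkh at a signal of 6080.8, the Pax gene eyg at 1974.8, the sulfotransferase gene pip at 557.4 and rib at 331.6. This call was lost without the peaks within 20 kb of fkh, an alternative chosen after the data were seen (adjusted Fisher's exact p = 0.059), in the 4766 strongest peaks (0.334) and within 5000 bp of a TSS (0.069). Stratified by gene length, the adjusted p was 0.0998 (Cochran-Mantel-Haenszel test). Of 35 genes of the secretory pathway machinery, 21 had a peak (60.0%, 42.1% to 76.1%, adjusted Fisher's exact p = 0.00312). Among these were TRAM, of the protein translocation channel, at 1363.4, the vesicle coat gene alphaCOP at 927.5, Trp1 at 807.3 and the chaperone gene Hsc70-3 at 799.2. The 12 salivary glue genes, the main secreted products of the gland, were not told apart from other genes (2 of 12, adjusted Fisher's exact p = 0.44). The glue peaks were at Sgs4, with a signal of 359.2, and Sgs3, with 163.3 and replicate ranks from 6373 to 15970.

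Of 28 genes of the ecdysone response, the steroid programme of this stage, 18 had a peak (64.3%, 44.1% to 81.4%, adjusted Fisher's exact p = 0.00189), with Kr-h1 at a signal of 911.3, the receptor coactivator gene tai at 786.4, the nuclear receptor gene Hr3 at 754.6 and Eip63E at 725.5. The call was lost in peaks shared by replicates 1 and 3, that is, without replicate 2 (adjusted Fisher's exact p = 0.112), in peaks present in all replicates (0.106) and when genes were stratified by length (adjusted p = 0.0805, Cochran-Mantel-Haenszel test). Of 25 autophagy genes, 14 had a peak (56.0%, 34.9% to 75.6%, adjusted Fisher's exact p = 0.0433), with Atg9 at 1168.2, Atg4b at 1130.7, Syx17 at 687.2 and Atg7 at 503.3. That call was lost without replicate 2 (adjusted Fisher's exact p = 0.0711), without replicate 3 (0.063), in peaks present in all replicates (0.0585), with the nearest gene per peak (0.0735) and with stratification by gene length (0.0851). Among genes with any pooled-list region, both the ecdysone and autophagy calls were lost. The odds ratios there were 1.175 (ecdysone response) and 0.913 (autophagy), against 3.999 and 2.825 among all genes. Cell death genes were not told apart from other genes (7 of 16, adjusted Fisher's exact p = 0.387). Their strongest peaks were at the caspase gene Drice, with 1638.1, the caspase inhibitor gene Diap1, with 927.4, Buffy, with 842.6, and the pro-death gene hid, with 590.1. None of the 10 late puff genes of the Eig71E cluster had a peak (adjusted Fisher's exact p = 0.0762; with gene bodies 0.0459). Insulin and TOR signalling had 14 of 28 members with a peak (adjusted Fisher's exact p = 0.0762), and passed the threshold with the nearest gene per peak (0.00885). Its strongest were the translation inhibitor gene Thor at 1412.9, the receptor gene InR at 1267.5, Akt at 1007.1 and Pdk1 at 844.2. Heat shock genes had 10 of 18 (adjusted Fisher's exact p = 0.0762), led by Hsp68 at 1434.9 and Hsp27 at 1251.9, and passed the threshold without replicate 3 (0.0408). The summits counted for Hsp68 and Hr3 lay 920 and 866 bp from those genes' own TSSs and within 500 bp of another gene's TSS.

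The lists of gut regulators and digestive enzymes went opposite ways, though whole prepupae cannot place these peaks in the gut. Of 22 gut regulators, 14 had a peak (63.6%, 40.7% to 82.8%, adjusted Fisher's exact p = 0.00741), with nub at a signal of 571.7, esg, a marker of gut progenitor cells, at 432.4, bowl at 402.4 and drm at 374.7. This call was lost without replicate 3 (adjusted Fisher's exact p = 0.0662), in the 4766 strongest peaks (0.0898) and with stratification by gene length (0.0998). Of 44 digestive enzyme genes, 3 had a peak (6.82%, 1.43% to 18.7%, adjusted Fisher's exact p = 0.00168): Jon65Ai, Jon25Biii and LysB. The summits counted for Jon65Ai and Jon25Biii lay 590 and 960 bp from those genes' own TSSs, each within 500 bp of another gene's TSS. With stratification by gene length the adjusted p of the digestive enzyme list was 0.0851 (Cochran-Mantel-Haenszel test). Among genes with any pooled-list region at a TSS, neither the regulators nor the enzymes passed the threshold.

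Ribosomal protein genes, used in all cells, and chemoreceptor genes, used in few, gave the smallest p of the 23 lists. Of 93 ribosomal protein genes, 58 had a peak (62.4%, 51.7% to 72.2%, adjusted Fisher's exact p = 6.64e-09), led by RpL34a at a signal of 1411.1 and RpL29 at 1164.5. Of 179 chemoreceptor genes, 8 had one (4.47%, 1.95% to 8.62%, adjusted Fisher's exact p = 1.16e-17). Genes of other tissues of the whole animal did not pass the threshold within 1000 bp of a TSS. The counts were 2 of 23 for epidermis and cuticle (adjusted Fisher's exact p = 0.056), 1 of 14 for haemocytes (0.139), 3 of 22 for muscle (0.172), 3 of 20 for testis (0.229), 3 of 19 for neurons (0.308) and 3 of 15 for fat body (0.473). They were 5 of 10 for trachea (0.387), 8 of 20 for the V-ATPase (0.49), 7 of 17 for the Fox family (0.473) and 4 of 10 for the Hox genes and their cofactors (0.513). Within 5000 bp of a TSS the neuron (adjusted Fisher's exact p = 0.00793), haemocyte (0.0157) and epidermis and cuticle lists (0.0157) passed as lower. Epidermis and cuticle also passed within 2000 bp (adjusted Fisher's exact p = 0.0132) and with gene bodies (0.0332), and testis in the 4766 strongest peaks (0.042). Among the 6046 protein-coding genes with any pooled-list region within 1000 bp of a TSS, ribosomal proteins were the 1 list that passed the threshold (odds ratio 4.59, adjusted Fisher's exact p = 0.0025). In that smaller set the odds ratio was 8.26 for the secretory pathway (3.33 among all genes) and 3.92 for salivary gland regulators (4.44), without a call (adjusted Fisher's exact p = 0.169 and 0.715). The remaining lists called above had 0.913 (autophagy), 1.175 (ecdysone response), 2.75 (gut regulators), 0.587 (digestive enzymes) and 0.390 (chemoreceptors), also without a call. Among all genes these lists had 2.825, 3.999, 3.885, 0.1615 and 0.102, in that order.

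**Figure D5:**
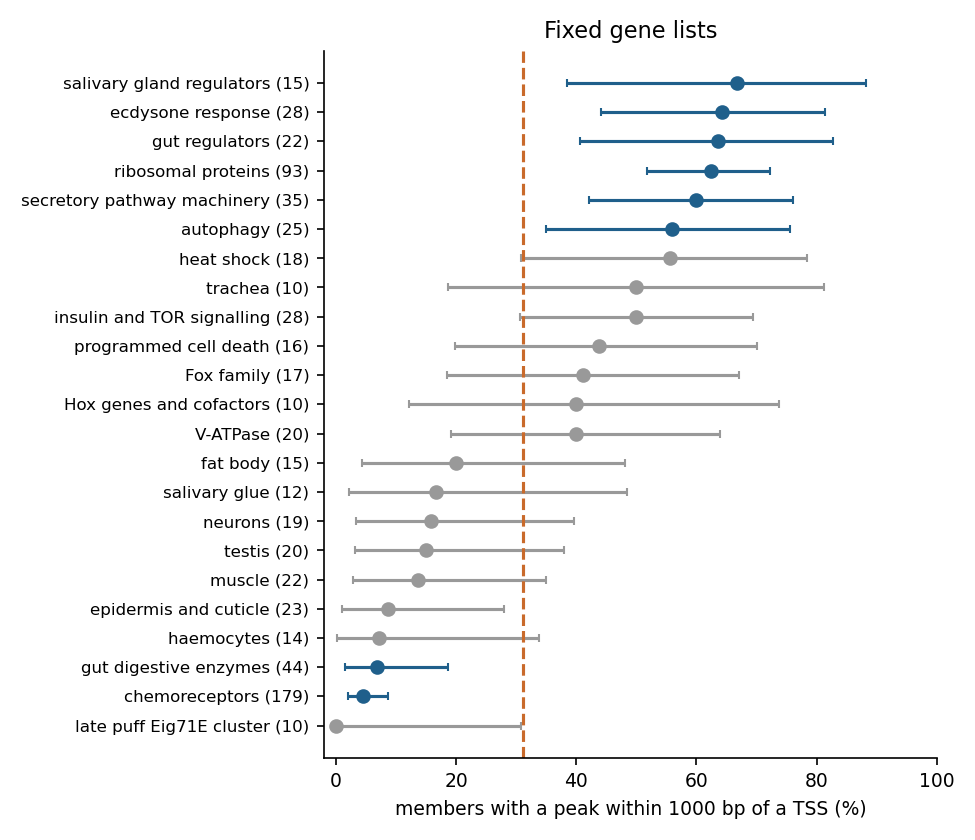
Share of the members of each fixed gene list with a peak within 1000 bp of a TSS (x axis, percent) with exact 95% intervals, the number of members in brackets, and the share of all 13968 protein-coding genes (31.1%) as a dashed line. Lists in blue had an adjusted Fisher's exact p under 0.05: 6 lay above the line and 2 below.

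Peaks were spread over the autosome arms at 71.2 to 76.1 per Mb of sequenced bases. The X chromosome had 63.2 per Mb, 15.6% of peaks on 17.1% of the length (adjusted exact binomial p = 7.05e-05), and chromosome 4 had 27.04 per Mb (adjusted exact binomial p = 1.15e-10). No peak was listed on the 3.41 Mb of the Y chromosome (adjusted exact binomial p = 7.98e-104). The expected shares came from length alone. Copy number in pools of males and females and the ease of mapping reads were not allowed for, so avoidance of a chromosome was not tested. Arms 2L, 2R and 3L were above their share of the length (adjusted exact binomial p from 1.05e-05 to 0.00904), and 3R did not pass the threshold (0.208). On the dm3 build the optimal list held 9305 peaks, with a strongest signal of 6075.3 against 6080.8 on dm6, and 1475 against 1483 of them were on the X chromosome.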

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

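The tests that left out close summits or the fkh locus were chosen only after the data were seen. Counting summits within 100 bp once removed no peak and so tests nothing. Of the 495 values under other settings for 52 results, 420 kept their direction and side of the threshold, stayed within 1.5 times (counts) or moved by less than the spread between replicates or the 95% interval (other values). With the 100 bp setting counted in, 457 values were kept, and 206 of these were for gene lists that had no call to lose. The cause of the changes below was not tested. Density per chromosome on dm3 was not run, since the lengths of its sequences are not used here, and no Eig71E gene had a pooled-list region to test. No paired analysis was possible because there is 1 group. The lists do not give read depth, and its effect on weak peaks was not tested. The forkhead word, its tie and that of promoters to strength, and the replicate overlap kept their calls under all settings run for them.

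In the 4766 strongest peaks, rank correlations were 0.731 (replicates 1 and 2) and 0.774 (1 and 3), class ratios 1.34 (5' UTR) and 0.963 (intron), and odds ratios 1.89 (salivary gland regulators), 2.63 (gut regulators) and 0.42 (Hox genes). Pearson's r of log2 signal was 0.816 for replicates 1 and 3. The share of peaks in all replicates was 98.2% with all regions, 42.6% with the 5000 strongest, 36.7% with 50% overlap, 57.7% with summits within 100 bp, and 77.4% to 80.5% with each replicate left out. In peaks present in all replicates the intron ratio was 0.990 and odds ratios were 2.76 (autophagy) and 2.24 (ecdysone response). Leaving out each replicate gave 0.983 to 1.01 for introns, 2.555 to 3.50 for autophagy, 2.08 to 3.197 for the ecdysone response and 2.77 to 4.02 for gut regulators. Without summits within 300 bp of a stronger one the intron ratio was 1.04, past the threshold.

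With a promoter window of 250 bp the ratios were 1.10 (intron) and 1.18 (other exon), and with 1000 bp 0.926 (intron) and 1.085 (5' UTR); both intron ratios passed the threshold, in opposite directions. Against the regions outside the optimal list they were 0.764 (intron), 1.06 (5' UTR) and 0.7565 (other exon).

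Within 5000 bp of a TSS 7170 genes had a peak, 5 lists were lower, and odds ratios were 3.80 (salivary gland regulators), 0.948 (V-ATPase) and 1.08 (fat body). With gene bodies 4 lists were lower. Among genes with a pooled-list region 1 list was higher and 0 lower, with odds ratios of 3.92 (salivary gland regulators), 8.26 (secretory pathway), 0.913 (autophagy and cell death), 1.175 (ecdysone response), 2.75 (gut regulators), 0.587 (digestive enzymes), 0.390 (chemoreceptors), 0.783 (V-ATPase), 0.489 (trachea) and 2.74 (muscle and testis, 0.5 added to each count). With the nearest gene per peak autophagy had 2.47. Stratified by gene length 2 lists were higher and 1 lower, with 3.59 (salivary gland regulators), 2.505 (autophagy), 2.87 (ecdysone response), 2.80 (gut regulators), 0.288 (digestive enzymes) and 0.781 (Hox genes). Without peaks within 20 kb of fkh, salivary gland regulators had 3.33. The fkh locus held 6 peaks within 5 kb and 27 within 20 kb. The density ratio of 3R was 1.08 in the strongest peaks and 1.05 in peaks present in all replicates, and passed the threshold in both.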

Other observations

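The tests of neighbouring summits' order, of the libraries' enrichment and of the ecdysone genes were chosen only after the result was seen. The genes with the most peaks within their body or 1000 bp of it were Eip75B, an ecdysone-induced nuclear receptor gene (FBgn0000568, 3L, 17950953 to 18064696), with 36 peaks, bun with 34, jing with 30, shn with 27, and CG1677 and SNF4Agamma with 25 each. The median of genes closest in length (100 on each side) was 3 for Eip75B, bun and jing and 2 for shn. These genes were chosen after their values were seen. The densest window of 50 kb, with 36 peaks, began at 28544862 on 3R and held fkh. The densest on 3L, with 31 peaks, began at 606878. All these counts are of summits and were not repeated with close summits left out.

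Among genes that make no protein, 80 of 290 tRNA genes had a peak within 1000 bp of a start (27.6%, exact 95% interval 22.5% to 33.1%). The shares were 23.0% of 269 snoRNA genes, 18.0% of 3289 other non-coding RNA genes, 5.15% of 330 pseudogenes and 0 of 99 rRNA genes. Over 2000 bp from any coding start they were 26.9% for tRNA, 16.5% for snoRNA, 11.0% for other non-coding RNA genes and 1.52% for pseudogenes. A peak near several of these genes counted for each of them, and the interval treats genes as independent. Ease of mapping reads was not allowed for, so the lack of peaks at rRNA genes does not show absence of binding. The differences between these classes were not tested. The DRE was found in 3.48% of promoter peaks and 0.283% of others (Fisher's exact p = 4.25e-36).

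The 28 ecdysone response genes held a median of 3 peaks per gene, against 1 (middle 95%, 0 to 2) in 10000 lists of genes matched on length, which argues against gene length as the whole of the pattern. Without the peaks within 1000 bp of a TSS the median was 1.5 against 0 (0 to 1), which also argues against peaks at promoters as the whole of the pattern. The mean was 5.96 per gene against 2.73 (adjusted permutation p = 0.0054), and EcR (18 peaks), tai (16), Hr4 (15) and ftz-f1 (13) followed Eip75B, while Eip93F, 65.4 kb long, had 0. The excess was not particular to this list: the mean was also above matched lists for autophagy (1.88 against 0.791) and ribosomal proteins (0.946 against 0.408), each with an adjusted permutation p of 0.0011, from the smallest p the draws can give, for the secretory pathway (0.0054) and for insulin and TOR, Fox and heat shock genes (0.0133 each), while neurons (0.474 against 2.63, 0.0011), chemoreceptors (0.0838 against 0.538, 0.0011) and digestive enzymes (0.0909 against 0.344, 0.0133) lay below and gut regulators had the same median of 3 but a mean with an adjusted permutation p of 0.256. Without the peaks within 1000 bp of a TSS autophagy remained above (0.68 against 0.164, adjusted permutation p = 0.0123) and neurons below (0.158 against 1.443, 0.0123). By the median, salivary gland and gut regulators also lay above their matched lists there (each 1 against 0, middle 95% 0 to 0). Their means did not pass the threshold (adjusted permutation p = 0.233 and 0.302). The numbers of peaks per gene are of summits and were not repeated with close summits left out. At TSSs, the call of the ecdysone list was lost when genes were stratified by length, as given above. No biological explanation was tested.

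The second rise of the forkhead word 200 to 220 bp left of summits went with the order of close summits. Of 692 pairs of neighbouring summits 150 to 300 bp apart in 1 interval, the left one was the stronger in 675 (97.5%, exact 95% interval 96.1% to 98.6%), at a median distance of 203 bp, and the share was 98.9% to 100% in the 3 replicates. Binding to DNA has no reason to prefer one side of the map, so the caller's splitting of wide intervals may have placed many weaker summits. The forkhead word was present at 46.4% of these weaker right-hand summits (lower bound of the exact 95% interval 42.6%). It was in 28.7% of windows at that distance right of single summits and in 32.7% of those to the left. Single meant that no other peak had the same interval, so close summits in overlapping intervals counted as single. The windows were not matched on interval width, so the higher share does not decide whether the weaker summits mark sites of their own. Single summits of similar signal had 58.2%, and only 17 weaker summits lay on the left, too few to compare.

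The strongest regions of the replicates differed in class. Among the 1000 strongest, promoters made up 48.9% in replicate 1, 61.4% in replicate 2 and 59.9% in replicate 3 (adjusted Fisher's exact p = 7.12e-08 for 1 against 2, 1.45e-06 for 1 against 3 and 0.522 for 2 against 3), and the forkhead word was at 74.6%, 67.4% and 68.4%; among the 9531 strongest, promoters made up 43.9%, 46.1% and 48.7% and the word was at 59.1%, 56.4% and 55.1%. At 107 promoter regions strong in replicates 2 and 3 but not in 1, the word was present at 57.9% of summits and 18.7% of flanks (exact McNemar p = 7.46e-09), which argues against general promoter signal without the word as their whole source, though the word was less frequent than at the 373 promoter regions strong in all 3 replicates (69.2%, Fisher's exact p = 0.0361). The ratio of the strongest to the median signal, which needs no shared scale, was 60.3, 51.8 and 45.8, so unequal enrichment of the libraries remains open, and with 3 libraries it cannot be told apart from a difference between the pools of animals. The strongest region in each replicate was the one at fkh, and whether the insertion covers it is unknown. The median includes background regions, so the ratio is a rough measure of enrichment. No biological explanation was tested, since the labels give no difference between the replicates.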
